A study of Arabidopsis thaliana with 39 samples.

How the data were processed

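The study measured RNA from Arabidopsis thaliana Col-0 seedlings, 14 days old, that had been given L-Glu (20 mM), urea (20 mM) or SA (1 mM) and harvested after 6, 12, 24 or 48 h, with a water-treated group at 0 h. Per the labels' protocols, seeds had 2 days of cold, plants grew at 23 degrees C on medium with 1% sucrose, and libraries were made by a high-throughput RNA-Seq method cited there. Groups and replicate numbers were taken from the sample titles, 3 libraries in each of 13 groups. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

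The authors deposited 1 table of signal values, a normalized value per gene and library, for 39 libraries and 20001 gene identifiers. All 39 value columns were matched to samples, from a letter for the treatment, the hours and the replicate number in each column name. The submitters' processing notes name TopHat2 2.1.0, HTSeq 0.6.0, edgeR 3.22.3 and the genome build TAIR10, without roles, settings or annotation, and how the deposited values were scaled is not given in the sources used here. Columns do not sum to a common total while their medians are close, and recomputed trimmed-mean scaling moved little, so the values look already brought to one effective library size. They are not whole numbers. The share of low values (up to 20 times the smallest) within 0.1 of a whole multiple of one step was 92.5% in L-Glu 6 h replicate 1, 90.5% in urea 12 h replicate 1 and 86.1% in urea 24 h replicate 1, but had a median of 18.2% over the columns. Columns with too few low values, or with an unsuitable step, entered this median as 0 by rule and were not measured. Whole reads were therefore not recovered, depth is unknown and no count test was run. In 16 columns no gene is at 0, and in the others between 134 and 657 genes are, so exact zeros were not read as absence. Strandedness of the libraries is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

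Gene names came from the RefSeq table of assembly TAIR10.1, used for names only. It matched 19887 identifiers and 114 stayed under their own identifier, among them 88 chloroplast and 13 mitochondrial ones. Values were compared as log2(value + 1), so a fold change of a gene with low values is understated. Genes with a value of at least 1 in at least 3 libraries were to be kept, and all 20001 passed. All 39 libraries entered one limma 3.58.1 fit in R 4.3.3, with 13 group means, an intensity trend in the prior variance, 26 residual degrees of freedom and two-sided moderated tests. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and a gene was called below 0.05. Errors of log2 fold changes are standard errors (SE) of this fit, and errors of values are standard deviations (SD) over 3 libraries. Each gene had one spread over the 13 groups, so a p-value also reflects libraries outside its comparison. The root mean square deviation of a library from its group mean was 0.412 to 0.524 in L-Glu at 48 h, against 0.309 to 0.365 in urea. SEs may thus be too small for L-Glu and too large for SA against urea.

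The 17 comparisons were L-Glu with urea, SA with urea and L-Glu with SA at each of 4 times, L-Glu with urea averaged over the times, each treatment averaged over the times with mock, and the change of the L-Glu minus urea difference from 6 to 48 h. The design, the alternatives, 16 gene lists and the rule for named genes were fixed before the data were examined. The rule took, among called genes with a mean of at least 10 in the higher group, the 10 highest and 10 lowest fold changes with one sign at all 4 times for the averaged L-Glu comparison, the 5 highest and 3 lowest with no overlap between replicates for L-Glu with urea at each time, the 3 highest and 3 lowest for the other single-time comparisons, and the 4 highest and 4 lowest for the averages against mock and for the change with time. Up to 4 members of each list could be named, and PR1, PR2, PR5, ICS1, PDF1.2a and VSP2 in any case. ICS1, PR1, PR2, PR5 and VSP2 are also given where they were not called. The lists were for the SA pathway, jasmonate, the ethylene and jasmonate defence branch, pattern-triggered immunity, glutamate receptor-like genes, glutamate metabolism, nitrate, ammonium and urea, amino acid transporters, photosynthesis, senescence, detoxification, abscisic acid, the clock, root markers, chaperones of the endoplasmic reticulum and heat shock. They held 291 members, of which 18 have no value in the table used here and 6 were left out because their symbol and identifier did not agree in the reference table, leaving 267. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 16 lists.

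Alternatives were pseudocounts of 0.25 and 4, no filter, a filter at 5, scaling factors recomputed as trimmed means (30% of log ratios and 5% of mean levels trimmed), quantile normalization, a fit of the compared groups alone, the replicate number as a block, a 2-fold threshold, leaving out single replicates and, for the overlap of L-Glu and SA, L-Glu against mock with SA against urea. Chosen after the data were seen were one total for every library, leaving out L-Glu 6 h or 48 h replicate 2 or mock 0 h replicate 2 from the averages, replicate 2 of L-Glu from the lists at 6 and 48 h, and single replicates from the overlap and the lists over the times. The fit was tested on simulated data for the 20001 genes with known changes in 67, 67 and 66 genes of each fold. The changed genes were drawn from those with a mean of at least 10. Each gene had the same normal spread in every library. For L-Glu against urea at 6 h it recovered 13.4% of the 1.5-fold, 56.7% of the 2-fold and 90.9% of the 4-fold changes and called 4 unchanged genes. For the average over the times it recovered 74.6%, 95.5% and 97.0% and called 5 unchanged genes. Far fewer genes were changed here than were called in the data. The rates hold for this setting only, and not for lower genes or for libraries with a larger spread.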

Results

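Gene expression was profiled by RNA sequencing in whole Col-0 Arabidopsis seedlings, 14 days old and grown in liquid culture, to find genes that respond to the amino acid L-glutamate (L-Glu). Seedlings received 20 mM L-Glu, 20 mM urea or 1 mM salicylic acid (SA, a plant defence hormone), and were sampled after 6, 12, 24 and 48 h. Together with a water-treated group at 0 h (mock), this gave 13 groups of 3 libraries, 39 in all. Urea was the treatment given at the same dose and times as L-Glu, and each time point was therefore compared with urea. No water group at a later time was analysed here, so treatment and time in culture cannot be separated in any comparison with mock. The deposited table held normalized values for 20001 genes. The values of a library summed to between 2445645 and 5886170, and the library medians lay between 46.4 and 56.9. These sums are not sequencing depth, which is unknown. In the L-Glu groups the sum was 2802446 ± 80841 at 6 h (SD, n = 3) and 5539052 ± 312913 at 24 h, against 2616574 ± 63091 for urea at 24 h.

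The libraries from 12 h on lay apart by treatment on the first 2 principal components of the log2 values. The first principal component carried 49.9% of the variance and set the L-Glu libraries apart, with values of 5.38 and 9.73 in replicates 1 and 3 at 6 h, between 104 and 118 at 12 h, between 199 and 208 at 24 h and between 168 and 196 at 48 h. The second carried 18.6% and set the SA libraries apart, with values from 47.9 at 6 h to 109 at 48 h. L-Glu 6 h replicate 2 lay at -43.0 on the first component, away from its group, and mock 0 h replicate 2 lay at -52.2, against -80.9 and -79.0 for the other mock libraries. L-Glu 48 h replicate 2 lay at 46.9 on the second component, near the lowest SA library and away from replicates 1 and 3 of its group at 3.24 and 3.63.

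**Figure D1:**
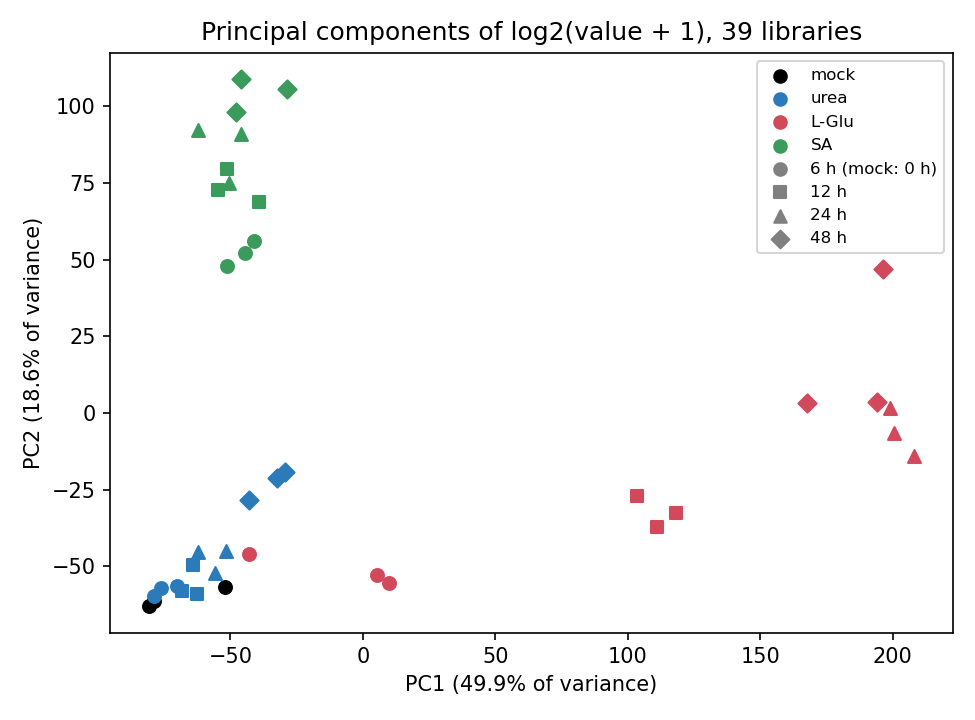
First (horizontal axis, 49.9% of the variance) and second (vertical axis, 18.6%) principal component of the log2 values, with each point a library coloured by treatment and shaped by time. L-Glu libraries from 12 h on lie to the right and SA libraries to the upper left.

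The comparison of L-Glu with urea over the 4 times asked which genes differ between L-Glu and urea at the same dose. RRTF1 (AT4G34410), a redox-responsive transcription factor, was higher by 9.33 ± 0.342 on the log2 scale (SE, adjusted p = 2.23e-22). The ethylene biosynthesis gene ACS8 (AT4G37770) was higher by 8.86, the transcription factor gene BHLH92 (AT5G43650) by 9.15, the alternative NADH dehydrogenase gene NDB4 by 8.41 and sks8 by 9.23. The highest change was that of AT5G55150, at 10.78 ± 0.393. Its value was 0.0871 ± 0.0829 in urea at 6 h and 20981 ± 1977 in L-Glu at 24 h (SD, n = 3). AT5G52050, AT1G74870, AT1G30190 and AT5G24640 were also among the 10 highest, at 8.94, 8.88, 8.67 and 8.53. Because these genes were near 0 in urea, the pseudocount of 1 holds their fold changes down. The lowest changes were those of the fructose-bisphosphate aldolase gene FBA5, at -4.65 ± 0.186, AT5G42530 at -4.37, AT3G62550 at -4.11, ESM1 at -4.10, the Rubisco small subunit gene RBCS2B (AT5G38420) at -4.07 and NCED4 at -4.02. SEN1 (AT4G35770), AT1G73120, AT2G32870 and AT2G26695 followed at -3.95, -3.89, -3.82 and -3.81. In all, 13888 of the 20001 genes passed an adjusted p of 0.05 in limma, 6609 higher and 7279 lower, and 5085 of them changed at least 2-fold. With every library at the same total, a choice made after the data were seen, 23.5% of called genes were higher against 47.6% as deposited. The median of all genes was -0.05 as deposited, -0.20 after quantile normalization and -0.53 at the same total.

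Members of 16 gene lists fixed beforehand were counted in L-Glu against urea over the 4 times, and 7 lists passed camera with a preset correlation between genes, none with an estimated one (lowest adjusted p = 0.0566). Of the 27 measured members of the salicylic acid pathway list, 23 were higher and 1 lower, and 24 passed when adjusted over the list alone. ICS1 (AT1G74710), which encodes the main enzyme of SA biosynthesis under attack, was higher by 5.11 ± 0.164. The glutaredoxin gene ROXY19 was higher by 7.15, FMO1, needed for systemic resistance, by 6.13, and SARD1, a regulator of ICS1, by 5.55. The marker gene PR1 (AT2G14610) did not pass, at 0.73 ± 0.43 (adjusted p = 0.128), but did without replicate 3 of every group, at 0.90 (adjusted p = 0.0271, with a range of 0.0271 to 0.445 over the alternatives). PR5 did not pass either, at -0.48 ± 0.259 (adjusted p = 0.0999), but did after quantile normalization, at -0.59 (adjusted p = 0.0368), with every library at the same total, at -0.85 (adjusted p = 0.00279), and without replicate 2, at -0.70 (adjusted p = 0.0437), with a range of 0.00279 to 0.548 over the alternatives. PR2 was higher by 1.39 ± 0.321. All 24 members of the list for pattern-triggered immunity were higher, and all 24 also adjusted over the list alone. Among them were the peptide precursor gene PROPEP3 at 5.14, PHI1 at 6.47 and the transcription factor genes WRKY53 at 5.35 and WRKY29 at 4.65. Of 19 jasmonate genes, 15 were higher and 3 lower (18 adjusted over the list alone), with LOX4 at 7.86, JAZ5 at 5.78 and JAZ7 at 5.39, while LOX2, a chloroplast lipoxygenase gene, was at -2.44. VSP2 was higher by 1.46 ± 0.367. All 4 measured genes of the ethylene and jasmonate defence branch were higher (4 adjusted over the list alone), led by ERF1 at 4.46, although only 2 of them passed with every library at the same total. PDF1.2a, which was to be reported in any case, has no value in the table used here.

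Of 24 detoxification genes, 21 were higher and none lower in L-Glu over the 4 times (21 adjusted over the list alone), with UGT74E2 at 7.11, GSTU11 at 6.69, ZAT12 at 6.08 and the alternative oxidase gene AOX1A at 4.47. With every library at the same total, 16 were higher and 2 lower. All 7 heat shock genes were higher (7 adjusted over the list alone), including HSFA2 at 3.59 and HSP21 at 3.23. At the single times, 0 of them were higher at 6 h, 1 at 12 h and 7 at both 24 and 48 h. None of the 27 photosynthesis genes was higher and 25 were lower (25 adjusted over the list alone), with RBCS3B at -3.39, Rubisco activase gene RCA at -3.26 and PSAE1 at -3.23. At 6 h only 1 of them was lower and 1 higher. Of 13 mitochondrial genes, 6 were higher and none lower in this comparison (median 0.50), while 0 were called at 6 h and at 12 h. Reads of the near-identical RBCS and LHCB1 copies and of neighbouring GSTU genes may have been split between copies, so their single values are uncertain. These 7 lists (SA pathway, pattern-triggered immunity, jasmonate, ethylene and jasmonate branch, detoxification, heat shock and photosynthesis) passed camera with a preset correlation between genes of 0.01, at adjusted p from 1.57e-15 to 0.0291. None passed with an estimated correlation, where the adjusted p was 0.0566 for SA pathway and pattern-triggered immunity, 0.0577 for photosynthesis, 0.118 for jasmonate, 0.149 for the ethylene and jasmonate branch, 0.162 for detoxification and 0.25 for heat shock.

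The other 9 lists did not pass camera in L-Glu against urea over the 4 times, and their members went both ways. Of 16 glutamate receptor-like genes, which encode amino acid-gated channels, 8 were higher and 3 lower (12 adjusted over the list alone), led by GLR2.8 at 5.92, GLR2.9 at 3.97 and GLR1.2 at 2.54. With every library at the same total, 5 were higher and 7 lower. Of 20 genes of glutamate metabolism, 8 were higher and 9 lower (17 adjusted over the list alone), and GAD4, a glutamate decarboxylase, was higher by 5.59 while the chloroplast enzymes GLU1 and GLN2 were at -3.77 and -2.32. The median of this list was 0.04, while its mean was -0.08 and camera's direction was down. Of 20 genes for nitrate, ammonium and urea, 6 were higher and 9 lower (16 adjusted over the list alone), with the ammonium transporter gene AMT2;1 at 2.14 and the nitrite reductase gene NIR1 at -2.08. Of 15 amino acid transporters, 8 were higher and 5 lower (13 adjusted over the list alone), with LHT1 at 3.79 and AAP2 at -1.56, and with every library at the same total 4 were higher and 7 lower. In the senescence list 5 of 14 were higher and 7 lower (12 adjusted over the list alone), with WRKY6 at 2.61 and SEN1 at -3.95. In the abscisic acid list 8 of 15 were higher and 1 lower (9 adjusted over the list alone), with the abscisic acid biosynthesis gene NCED3 at 1.69, and 3 and 5 with every library at the same total. In the clock list 8 of 12 were higher and 3 lower (11 adjusted over the list alone), with PRR9 at 2.34 and PRR7 at -1.12, and 4 and 4 after quantile normalization and 4 and 5 with every library at the same total. Of 10 chaperones of the endoplasmic reticulum, 7 were lower and 2 higher (9 adjusted over the list alone), with the stress transcription factor gene BZIP60 at 5.13 and CNX1 at -1.09. Of 13 root markers, 2 were higher and 4 lower (5 adjusted over the list alone), with PYK10 at 1.03 and PLT1 at -1.02, and 1 and 9 with every library at the same total.

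**Figure D2:**
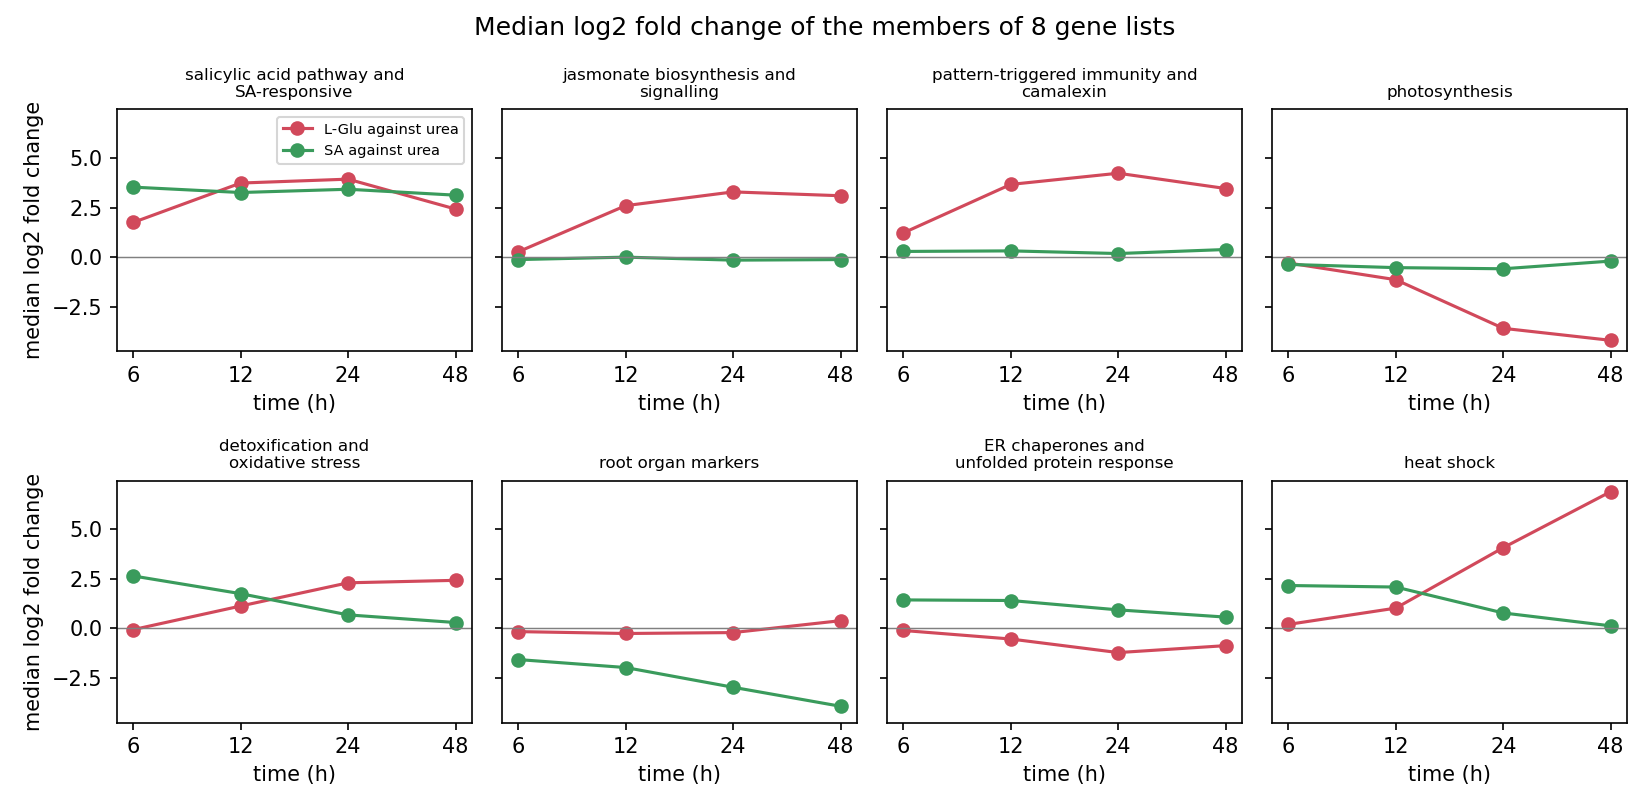
Median log2 fold change (vertical axis) of 8 gene lists at each time in hours (horizontal axis), for L-Glu against urea and SA against urea, with the values as deposited. At 48 h the photosynthesis list lies at -4.21 in L-Glu and the root markers at -3.94 in SA.

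At 6 h NRT1.8 (AT4G21680), a nitrate transporter gene, was higher in L-Glu than in urea by 6.32 ± 0.553 (adjusted p = 1.86e-09), AT3G25240 by 5.99, AT5G55150 by 5.81 and AT1G23110 by 5.69, and ACS8 was also among the 5 highest. BT2 was lower at -2.85, with AT2G21210 at -2.71 and AT2G26695 at -2.67. In the SA pathway list 17 of 27 members were higher and none lower (23 adjusted over the list alone), with PBS3 at 5.12, ICS1 at 3.77 and PR1 at 3.66 ± 0.86 (adjusted p = 0.00332). PR1 lost its call in a fit of these groups alone (adjusted p = 0.055, with a range of 0.000151 to 0.055 over the alternatives). Its values were low, 42.5, 74.75 and 2.92 in L-Glu replicates 1, 2 and 3, against 4335 to 4916 in SA at 6 h. PR1 was thus highest in replicate 2, whose response was weaker in other genes. Of 24 pattern-triggered immunity genes, 15 were higher (18 adjusted over the list alone), with FRK1 at 3.88. The SA pathway list passed camera also with an estimated correlation (adjusted p = 0.00595), and the list for pattern-triggered immunity did not (adjusted p = 0.0652 with an estimated correlation). In all, 2304 genes passed, 1673 higher and 631 lower, 1280 of them at least 2-fold. Replicate 2 of L-Glu at 6 h showed a weaker response than replicates 1 and 3, and 2882 genes passed without it. The count was 1435 without L-Glu replicate 1, 1347 without L-Glu replicate 3 and 1437 in a fit of these groups alone, and 56.4% of called genes were higher after quantile normalization against 72.6% as deposited.

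At 12 h RRTF1 was higher in L-Glu than in urea by 10.57 ± 0.684 (adjusted p = 1.47e-14), AT5G55150 by 11.05, AT5G52050 by 10.95, ACS8 by 10.15 and AT1G30190 by 10.09. AT5G62360 was at -4.76, GASA6 at -4.48 and AT1G10640 at -4.13. The SA pathway list had 22 members higher and 1 lower of 27 (23 adjusted over the list alone), and pattern-triggered immunity 23 of 24 higher (23 adjusted over the list alone), both also past camera with an estimated correlation (adjusted p = 0.0285). Of the photosynthesis genes, 21 of 27 were lower and 1 higher (22 adjusted over the list alone), a list call that was lost (adjusted p = 0.27 with an estimated correlation). In all 9540 genes passed, 5166 higher and 4374 lower, 5447 at least 2-fold. The share of higher calls was 54.2% as deposited, 37.6% after quantile normalization and 28.4% with every library at the same total. These scalings moved the median of all genes from -0.04 to -0.29 and -0.47.

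At 24 h BHLH92 was higher in L-Glu than in urea by 13.03 ± 0.702 (adjusted p = 2.25e-17), AT5G55150 by 14.04, sks8 by 13.28, AT1G74870 by 12.68 and NDB4 by 12.13. The chloroplast aldolase gene FBA1 was at -6.36, FBA5 at -6.78 and RBCS2B at -6.68. All 24 genes of pattern-triggered immunity were higher (24 adjusted over the list alone), with PHI1 at 9.15, and all 7 heat shock genes (7 adjusted over the list alone). Of 27 photosynthesis genes, 25 were lower and none higher (25 adjusted over the list alone), with PSBO2 at -5.44. In the same libraries 5 of 13 mitochondrial genes were higher and none lower (median 0.77). No list passed with an estimated correlation, where the adjusted p was 0.0563 for pattern-triggered immunity and photosynthesis and 0.281 for heat shock. In all 12126 genes passed, 5861 higher and 6265 lower, 7978 of them at least 2-fold. With every library at the same total 17.9% of called genes were higher, against 5861 of the 12126 as deposited. The median of all genes was -0.10 as deposited, -0.27 after quantile normalization and -1.10 at the same total.

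At 48 h all 27 photosynthesis genes were lower in L-Glu (27 adjusted over the list alone), also past camera with an estimated correlation (adjusted p = 0.0317). RBCS2B was at -8.49 ± 0.314 (adjusted p = 1.31e-21), with a value of 2862 ± 743 in urea and 7.47 ± 4.27 in L-Glu (SD, n = 3). The photorespiration gene GOX1 was at -7.69 and AT5G42530 at -8.65. HSP23.6-MITO, a small heat shock protein gene of mitochondria, was higher by 11.31, DLAH by 11.24, AT5G55150 by 12.22, BHLH92 by 11.08 and RRTF1 by 11.02. All 7 listed heat shock genes were higher (7 adjusted over the list alone), with HSP21 at 7.30 (adjusted p = 0.0710 with an estimated correlation). VSP2, a jasmonate-responsive storage protein gene, was higher by 4.81 ± 0.735. PR1 stood at 1.17 ± 1.42 in L-Glu and 3.85 ± 5.13 in urea (SD, n = 3) and did not differ past the threshold (adjusted p = 0.439), while ICS1 stood at 2001 ± 1236 and 141 ± 63.6. In the L-Glu libraries in which these groups moved, genes of the mitochondrial genome held 0.541%, 0.460% and 0.249% of all values, against 0.0919%, 0.0480% and 0.0534% in urea. Nearly all of this share came from ATMG00020 and ATMG01390. L-Glu replicate 2, which stood apart, listed 443 genes at 0 and replicates 1 and 3 none, against 226, 0 and 186 in urea. Without it 27 photosynthesis genes were lower and 7 heat shock genes higher. In all 10575 genes passed, 5050 higher and 5525 lower, 6896 at least 2-fold, and 9282 passed without L-Glu replicate 2. The share higher was 47.8% as deposited and 25.6% with every library at the same total, which moved the median of all genes from -0.06 to -0.54.

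**Figure D3:**
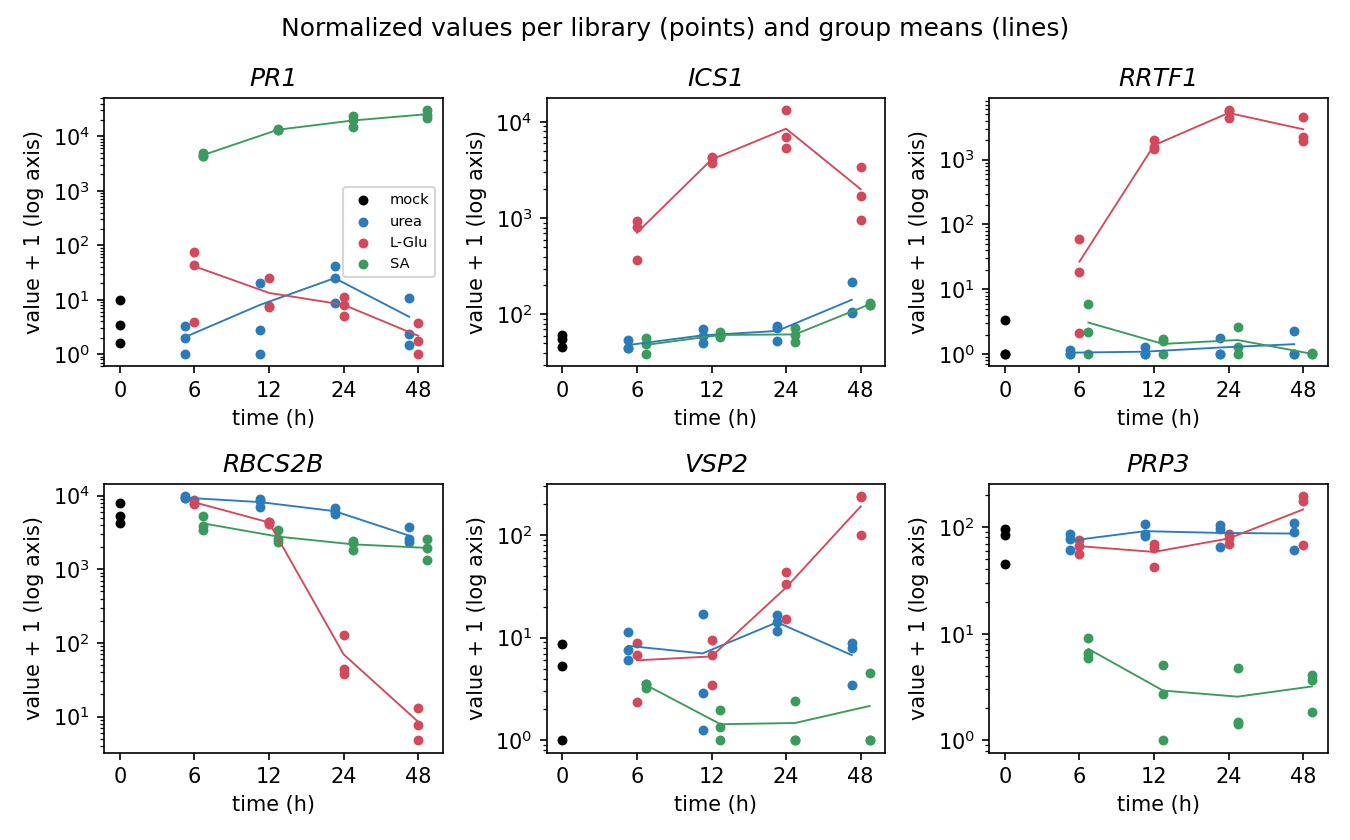
Normalized values plus 1 (vertical log axis) of 6 genes at each time in hours (horizontal axis), with points for libraries, lines joining group means and colours for treatments. The mean of PR1 is 25647 in SA at 48 h and that of ICS1 8506 in L-Glu at 24 h.

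The change of the L-Glu minus urea difference from 6 to 48 h was tested directly. Photosynthesis genes changed downward in 26 of 27 cases (26 adjusted over the list alone), also past camera with an estimated correlation (adjusted p = 0.0117), with RBCS2B changing by -8.29 ± 0.445 (adjusted p = 2.36e-16) and RBCS1B by -7.82. All 7 heat shock genes changed upward (7 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation). The change was 11.04 for HSP23.6-MITO, 9.03 for DLAH, 8.55 for SDR2 (AT3G51680) and 8.52 for HSP17.6A, and -8.31 for AT5G42530 and -7.96 for AT4G12500. Without L-Glu 48 h replicate 2, which stood apart from its group, 26 photosynthesis genes changed downward and 7 heat shock genes upward. Of 13 genes of the mitochondrial genome, 7 changed upward and none downward in the same comparison (median 2.37). PR1 moved by -4.48 ± 1.22 (adjusted p = 0.00386) and ICS1 by -0.05 ± 0.463 (adjusted p = 0.946). The PR1 change is one between low values, 42.5, 74.75 and 2.92 in the L-Glu libraries at 6 h and 0.77, 0 and 2.75 at 48 h. In all 7101 genes passed, 3276 higher and 3825 lower. With every library at the same total 20.9% of called genes were higher, against 46.1% as deposited, and the median of all genes moved from -0.07 to -0.56.

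SA was compared with urea at the same times. The doses differed, 1 mM for SA and 20 mM for urea, and the difference also holds any response to urea, which differed from mock in 2788 genes. PR1 was higher at each time, by 11.25 ± 0.86 at 6 h, 11.75 at 12 h, 9.86 at 24 h and 12.90 at 48 h (adjusted p = 1.63e-13 at 48 h). ARD3 (AT2G26400), a gene of methionine recycling, was higher by 10.10, 10.62, 9.71 and 10.21 at these times, and PCR1 (AT1G14880) by 10.84, 10.65, 10.02 and 10.51. ICS1, in contrast, differed by -0.01 ± 0.327 at 6 h and -0.07 ± 0.327 at 48 h (adjusted p = 0.991 and 0.902). PR5 was higher by 3.94 and PR2 by 3.13 at 48 h. VSP2 was lower at 48 h, at -1.92 ± 0.735 (adjusted p = 0.047), a call lost with a pseudocount of 4 (adjusted p = 0.109), after quantile normalization (0.193), without urea 48 h replicate 2 (0.125) or 3 (0.152) and without SA 48 h replicate 1 (0.183) or 3 (0.175), within a range of 0.0119 to 0.193 over the alternatives. Of 27 SA pathway genes, 21 were higher and 1 lower at 6 h (23 adjusted over the list alone) and 25 higher at 48 h (25 adjusted over the list alone), past camera also with an estimated correlation (adjusted p = 0.00601 and 0.000848). At both 12 and 24 h 23 were higher and none lower (23 adjusted over the list alone; adjusted p = 0.00372 and 0.0016 with an estimated correlation). The lowest named genes at 6 h were PRP1 at -4.94, the cell wall gene XTH12 at -4.60 and AT1G54660 at -4.24. At 12 h they were sks15 at -6.05, sks16 at -5.84 and AT3G19430 at -5.67. At 24 h they were AT1G52070 at -7.20, AT1G52060 at -6.38 and AT1G73120 at -6.10, and at 48 h AT1G52070 at -7.77, AT5G26260 at -6.69 and AT5G54370 at -6.36.

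Markers of root tissue were lower in the same SA libraries in which these gene groups moved. Of 13 root markers, 8 were lower and 1 higher at 6 h (10 adjusted over the list alone) and 11 lower at 48 h (11 adjusted over the list alone), past camera also with an estimated correlation (adjusted p = 0.0314 and 0.000848). At 12 h 8 and at 24 h 10 were lower (9 and 10 adjusted over the list alone; adjusted p = 0.00812 and 0.0016 with an estimated correlation). At 48 h the root hair genes PRP3, LRX1 and EXPA18 were at -4.80 ± 0.448, -4.31 and -4.29, and the endodermal gene CASP1 was at -4.23. All 10 chaperones of the endoplasmic reticulum were higher at 6 h (10 adjusted over the list alone; adjusted p = 0.0108 with an estimated correlation), with CRT3 at 1.58, all 10 at 12 h (10 adjusted over the list alone; adjusted p = 0.00812 with an estimated correlation), 8 at 24 h (9 adjusted over the list alone; adjusted p = 0.0722 with an estimated correlation) and 7 of 10 at 48 h (8 adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). Detoxification genes were higher in 16 of 24 cases and lower in 2 at 6 h (20 adjusted over the list alone; adjusted p = 0.0786 with an estimated correlation), with GSTU25 at 5.50 and UGT73B4 at 4.84, and higher in 7 and lower in 2 at 48 h (9 adjusted over the list alone). All 7 heat shock genes were higher at 6 h (7 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with HSP17.6II at 5.94 and HSP21 at 4.21, and 2 at 48 h (2 adjusted over the list alone). In all 5882 genes passed at 6 h, 6360 at 12 h, 6113 at 24 h and 5683 at 48 h, of which 3177, 3413, 3333 and 3290 changed at least 2-fold. At 48 h 29.2% of called genes were higher with every library at the same total, against 47.5% as deposited, and the median of all genes moved from 0.01 to -0.16. At 24 h the shares were 37.4% and 49.3%, and the median moved to -0.11.

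L-Glu and SA were compared directly to ask where the responses differ. PR1 was lower in L-Glu than in SA, at -7.60 ± 0.86 at 6 h and -13.72 ± 0.86 at 48 h (adjusted p = 1.01e-15). PCR1 was at -9.91 at 6 h and -11.16 at 48 h, and at 6 h AT3G28510 was at -9.31 and ARD3 at -8.27. At 12 h PR1 was at -10.21, PCR1 at -10.37 and LURP1 at -9.09, and at 24 h PR1 was at -11.29, PCR1 at -9.87 and AT2G25510 at -9.62. ICS1 was higher in L-Glu by 3.78 at 6 h and 6.05 at 12 h. ACS8, among the 3 highest at 6 h, was higher in L-Glu by 10.08 at 12 h, AT1G23110 by 5.73 and AT3G25240 by 5.42 at 6 h, RRTF1 by 10.20 at 12 h and 11.40 at 48 h, BHLH92 by 10.20 at 12 h and 13.51 at 24 h, DLAH by 13.12 at 24 h, and AT5G55150 by 13.04 at 24 h and 12.45 at 48 h. AT5G42530 was at -11.11 at 48 h. VSP2 was higher in L-Glu by 6.74 and PR5 at -5.19 at 48 h, and PR2 at -1.89, a call lost without L-Glu 48 h replicate 1 (adjusted p = 0.0969, with a range of 0.00326 to 0.0969 over the alternatives). BHLH92, among the 3 highest at 48 h, was listed at 0 in all SA libraries at that time.

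Of the 19 jasmonate genes, 15 were higher and 3 lower in L-Glu than in SA at 48 h (18 adjusted over the list alone; adjusted p = 0.110 with an estimated correlation), with LOX4 at 6.79 and LOX2 at -6.53. All 27 photosynthesis genes were lower (27 adjusted over the list alone) and 11 of 13 root markers higher and 1 lower (12 adjusted over the list alone), both past camera with an estimated correlation (adjusted p = 0.0312). These are the L-Glu libraries with 0.249% to 0.541% of values from mitochondrial genes, nearly all from ATMG00020 and ATMG01390, against 0.0402% to 0.0482% in SA. Without replicate 2 of L-Glu, 27 photosynthesis genes were lower and 11 root markers higher. At 6 h 9 of 10 chaperones of the endoplasmic reticulum were lower in L-Glu and none higher (9 adjusted over the list alone), led by BIP3 at -4.87 ± 0.561, the only list at that time past camera with an estimated correlation (adjusted p = 0.0336). Without L-Glu 6 h replicate 2, 9 were lower and 1 higher. Root markers differed at 6 h too, with 7 of 13 higher in L-Glu and 1 lower (9 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). In the SA pathway list 9 of 27 genes were higher and 17 lower at 6 h (26 adjusted over the list alone), past camera downward (adjusted p = 8.19e-05, and adjusted p = 0.206 with an estimated correlation). At 48 h 10 were higher and 13 lower (23 adjusted over the list alone), and the list did not pass camera at 12, 24 or 48 h (adjusted p = 0.835, 0.329 and 0.639). In all 6664 genes passed at 6 h, 10491 at 12 h, 12496 at 24 h and 11787 at 48 h, of which 3468, 6317, 8591 and 7893 changed at least 2-fold. The share of higher calls at 12, 24 and 48 h was 55.5%, 50.7% and 49.8% as deposited and 35.2%, 22.5% and 36.1% with every library at the same total, and 40.3% at 12 h after quantile normalization. The median of all genes, 0.07, 0.01 and -0.01 as deposited, moved to -0.29, -0.89 and -0.32 at the same total and to -0.20, -0.23 and -0.15 after quantile normalization.

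The L-Glu and SA responses overlapped, and the sharing of urea libraries has to be set beside that. At 6 h, 694 genes were higher and 129 lower in both against urea, 155 in opposite directions. Independent lists of the same sizes would share 266 and 85.3. At 12 h, 1444 were higher and 1097 lower in both and 828 opposite, against 837.9 and 681 for independent lists. At 24 h the counts were 1335, 1385 and 1219, against 883.5 and 970.4. At 48 h they were 1004, 1015 and 1229, against 682 and 824, and in a fit of the 3 groups alone 1327 genes were shared in direction against 2019. Simulated groups without any effect, set against common urea libraries, shared 0 genes, but at most 0.3 genes were called in them on average, so this 0 gives no chance level for the overlap. Across genes, which are not independent replicates, the fold changes correlated at 0.36 at 6 h and 0.13 at 48 h, while simulated groups without effect gave 0.50. The covariance was 0.25 at 6 h, 0.47 at 12 h, 0.47 at 24 h and 0.23 at 48 h, against a simulated 0.06 at each time. The 3 urea libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. With L-Glu set against mock at 0 h instead, so that no library was shared but time in culture entered, 726, 2449, 2734 and 2356 genes changed in one direction in both at 6, 12, 24 and 48 h, and 228, 968, 1304 and 1430 in opposite directions. Of the former, 639, 1416, 1421 and 1193 were higher, against 267.5, 857.3, 916.1 and 813.8 for independent lists. The lower ones numbered 87, 1033, 1313 and 1163, against 83.0, 712, 989.8 and 940.6.

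Against mock at 0 h, each treatment was averaged over the 4 times. With urea, the sugar-starvation gene DIN2 was higher by 5.13 ± 0.461 (adjusted p = 1.83e-09), CYP71A12 by 5.06, the potassium transporter gene HAK5 by 4.27, and AT1G26380 was also among the 4 highest. AT3G10040 was at -4.03, GSTF14 at -3.18, AT4G33560 at -3.10 and CYP79F1 at -3.10. Among nitrogen genes, the urea transporter gene DUR3 was at 2.08 and NRT2.5 at 2.96. Of 24 detoxification genes, 14 were higher and none lower (18 adjusted over the list alone), with GSTU4 at 2.96, and of 14 senescence genes 7 were higher and 1 lower (10 adjusted over the list alone), with SAG13 at 3.29. Of 15 amino acid transporters, 7 were higher and 1 lower (9 adjusted over the list alone), with CAT1 (AT4G21120) at 2.72, and of 12 clock genes 5 were higher (7 adjusted over the list alone), with PRR9 at 2.21, a call lost without replicate 1 (adjusted p = 0.064, with a range of 9.59e-06 to 0.064 over the alternatives). These 4 lists passed camera also with an estimated correlation (adjusted p = 0.0266). Of 27 photosynthesis genes 11 were lower and none higher (22 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation), and 4 were lower after quantile normalization. In all 2788 genes passed, 856 of them at least 2-fold, with 1170 without replicate 1, 1590 without replicate 2 and 1308 without replicate 3 of all these groups. Without mock 0 h replicate 2, which stood apart from its group, 1929 passed. The share of higher calls was 55.9% as deposited and 68.9% with every library at the same total.

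With L-Glu against mock, AT5G55150 was higher by 10.53 ± 0.622 (adjusted p = 3.32e-16), the receptor-like kinase gene CRK36 by 9.73, the peroxidase gene PER4 by 9.31 and AT4G12735 by 8.81, and CYP79F1, a gene of glucosinolate synthesis, was at -5.07, AT3G05730 at -4.43, AT2G21210 at -4.30 and AT3G54830 at -4.23. All 27 photosynthesis genes were lower (27 adjusted over the list alone), with PSBO2 at -3.48, and 24 of 27 SA pathway genes were higher and 1 lower (26 adjusted over the list alone), with FMO1 at 7.56. All 24 genes of pattern-triggered immunity were higher (24 adjusted over the list alone), with PROPEP3 at 6.19, and these 3 lists passed camera also with an estimated correlation (adjusted p = 0.0303). So did the detoxification list (adjusted p = 0.0499), with 23 of 24 genes higher (24 adjusted over the list alone). Of 13 mitochondrial genes, 6 were higher and none lower. In all 11516 genes passed, 5984 at least 2-fold. As deposited 5762 were higher and 5754 lower, and the share higher was 39.3% after quantile normalization and 27.3% with every library at the same total. These scalings moved the median of all genes from -0.03 to -0.20 and -0.44. With SA against mock, PR1 was higher by 11.75 ± 0.68 (adjusted p = 1.07e-15), AT3G28510 by 11.04, ARD3 by 10.30 and PCR1 by 10.27, and AT1G52060 was at -5.22, AT1G52070 at -5.10, AT1G52050 at -4.82 and sks15 at -4.79. Of 27 SA pathway genes, 23 were higher (24 adjusted over the list alone; adjusted p = 0.00772 with an estimated correlation), with NIMIN1 at 7.52. Of 14 senescence genes, 10 were higher and 1 lower (11 adjusted over the list alone), with SAG13 at 5.63, and 9 of 13 root markers were lower (9 adjusted over the list alone), with PRP3 at -4.45. In the detoxification list 22 of 24 were higher (22 adjusted over the list alone), as were all 10 chaperones of the endoplasmic reticulum (10 adjusted over the list alone), and these 4 lists had an adjusted p = 0.0334 with an estimated correlation. Photosynthesis genes were lower also with SA against mock, in 26 of 27 cases (26 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation). Against urea at the same times, only 5, 9, 13 and 2 of the 27 were lower with SA at 6, 12, 24 and 48 h. Treatment and time in culture cannot be separated in the comparison with mock. In all 10054 genes passed, 4648 at least 2-fold.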

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

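The test of an exchange with a mock library, and the look at which splits kept the L-Glu 48 h libraries together, were chosen after the result was seen. The L-Glu minus urea difference was tested for a change from 6 to 48 h, and 7101 genes differed between the times. The strongest changes on the log2 scale were 11.04 for HSP23.6-MITO, 9.03 for DLAH, 8.55 for SDR2, 8.52 for HSP17.6A, -8.31 for AT5G42530, -8.29 for RBCS2B, -7.96 for AT4G12500 and -7.82 for RBCS1B. Of 100 random splits of these 12 libraries, the real one included, 6 called at least as many genes, and the highest other split called 9063. All 5 others of these were among the 18 splits that kept the 3 L-Glu 48 h libraries on one side of the contrast, whose median was 6034, while splits with these libraries on both sides called 1632 genes at most. Such splits carry the L-Glu difference at 48 h, a structure of the samples, so this count does not show whether chance can be excluded.

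Other splits of the samples were counted for each comparison. For the average of L-Glu against urea the real split called 13888 genes and the highest of the others 6530. Only 1 of 100 splits, the real one, gave so many. The same held for urea against mock, with 2788 genes and 330 at most in another split. It also held for L-Glu against mock, with 11516 and 10131, and for SA against mock, with 10054 and 3981. However, the other splits mix libraries of different times and treatments within a group, which raises the spread. These counts therefore do not show whether chance can be excluded. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 2304 and 513, 9540 and 1, 12126 and 0, and 10575 and 36 for L-Glu against urea at 6, 12, 24 and 48 h. They were 5882 and 1, 6360 and 4, 6113 and 0, and 5683 and 3 for SA against urea, and 6664 and 291, 10491 and 0, 12496 and 1, and 11787 and 86 for L-Glu against SA.

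L-Glu 6 h replicate 2 showed a weaker response than replicates 1 and 3. Over 386 genes with a value of at least 50 in both of these and at least 4-fold the urea value plus 1, it kept a median fraction of 0.12 of their rise. Because the genes were chosen by their values in replicates 1 and 3, the choice itself favours a low fraction in replicate 2. A full exchange with mock 0 h replicate 2 needs a slope near 1 of that library on the 6 h response. The slope was only 0.164, which argues against a full exchange. A partial exchange between these libraries was not tested, and this slope does not decide it. A mixture with material without L-Glu predicts one fraction for all genes, taken as a difference under 0.1. A slower response predicts a fraction lower by more than 0.1 for genes that rise more to 12 h. The fraction differed between these genes and the rest by -0.0746 (bootstrap interval -0.112 to -0.0315), so both stay open and cannot be told apart, because the interval includes the bound of -0.1.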

How the results depend on the processing

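One total for every library, the averages without L-Glu 6 h or 48 h replicate 2 or mock 0 h replicate 2, the lists at 6 and 48 h without replicate 2 of L-Glu at that time, and the lists over the times and the overlap with replicates left out, were chosen after the data were seen. The planned count test was not run, since whole reads were not recovered, and leaving the filter out changed nothing because it removed no gene. Of 224 alternative values of the counts of genes or lists (leave-one-out aside), 203 lay within 1.5 times the reported one and 21 did not. A 2-fold threshold gave 1280, 5447, 7978 and 6896 genes for L-Glu against urea at 6, 12, 24 and 48 h, 3177, 3413, 3333 and 3290 for SA against urea, 3468 and 6317 for L-Glu against SA at 6 and 12 h, 5085 for the average of L-Glu against urea, and 856, 5984 and 4648 for urea, L-Glu and SA against mock. The shared genes of L-Glu and SA then numbered 458, 1144, 1284 and 1074. Fits of the compared groups alone gave 1437 genes for L-Glu against urea at 6 h and 1327 shared genes at 48 h, and with an estimated correlation 0 of the 7 lists of the L-Glu average passed. The 2-fold threshold counts a part of the called genes. For the lists and the fits of the compared groups alone, which raised other counts (7146 against 5882 genes for SA against urea at 6 h), the cause was not tested.

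Leaving out single replicates gave 1347 to 2882 genes for L-Glu against urea at 6 h and 1170 to 1929 for urea against mock (2304 and 2788 as reported). The counts of the other comparisons, of the shared genes at each time and of the lists of the L-Glu average stayed within 1.5 times the reported ones. The average of L-Glu against urea called 13814 genes without L-Glu 6 h replicate 2 and 13703 without L-Glu 48 h replicate 2. Among 223 results for single genes, 3514 alternative values were computed and none reversed. Outside leave-one-out 2225 kept their side of the threshold, 3 lost and 2 gained a call, and with replicates left out 1276 kept it, 6 lost and 2 gained one. These were for VSP2, PR1, PR5, PR2 and PRR9.

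With the replicate number as a block the counts were 2533, 9829, 12324 and 10808 for L-Glu against urea at the 4 times and 14046 for their average, and no count of the other comparisons moved by more than 1.5 times. Of 234 pairs of libraries with equal numbers, 36 had deviations that correlated above 0.1 across genes. Pairs with equal numbers correlated at 0.0476 on average (lowest -0.123), against -0.0238 for unequal numbers. However, 30 of 39 libraries correlated best with a library of their own number, more than unrelated numbers would give. Equal numbers thus appear to share a weak effect. The main fit, as planned, did not pair the samples by number and leaves this effect out. Depth is unknown and limits the low genes most, whose fold changes depend on the pseudocount.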

Other observations

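The tests of the scaling, of the chloroplast genes and of the share of root tissue were chosen after the result was seen. Genes of the mitochondrial genome were higher in L-Glu than in urea at 48 h. Of 13 measured, 7 were higher and none lower (limma, adjusted over all genes), with a median log2 fold change of 2.01. The values of ATMG01390 were 357 ± 157 in urea and 5926 ± 1558 in L-Glu (SD, n = 3), and those of ATMG00020 were 1225 ± 499.6 in urea and 8333 ± 2737 in L-Glu, with log2 fold changes of 4.11 ± 0.26 and 2.78 ± 0.257. These genes were chosen after their values were seen, and from background knowledge encode mitochondrial ribosomal RNA. The share of all values from mitochondrial genes was 0.541%, 0.460% and 0.249% in the 3 L-Glu libraries, against 0.0919%, 0.0480% and 0.0534% in urea. Nearly all of it came from ATMG00020 and ATMG01390. The next highest mean was that of ATMG00030, at 14.4 in urea and 165 in L-Glu. The share thus says little about the other mitochondrial genes.

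With every library at the same total the median of these genes was 1.54, and 7 of 13 were still higher. Its standard error of 0.389 treats the genes as independent, which they are not. Mean totals at 48 h were 3604752 in L-Glu and 2525682 in urea, and these fixed the size of the shift in advance. The result therefore shows only that this rescaling does not remove the rise of the mitochondrial genes. Other effects of the authors' scaling were not excluded. The 88 chloroplast genes had a median of -0.26 and so did not rise with them. Nuclear photosynthesis genes were lower in the same libraries, so chloroplast transcripts may have fallen as well. Their median therefore does not decide whether more organelle RNA of any kind was present. A rise of mitochondrial transcripts within cells and a change in how they enter the libraries both stay open, and neither was tested.

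Root markers were lower in SA than in urea, averaged over the times, with a median log2 fold change of -2.40 over 13 genes. A smaller share of root tissue would lower them alike if they were expressed in root alone, which was not tested. SCR was at 0.12 ± 0.0927, SHR at -0.22 ± 0.133 and RHD2 at -0.32 ± 0.125, although its mean value was 57.2 in urea and 61.4 in SA, since it was higher at 6 h (1.36) and lower at 24 h (-1.51). PRP3 was at -4.69 ± 0.224 and LRX1 at -4.00 ± 0.209. These 5 genes lay further than 1 from the median by more than 2 standard errors. That argues against a smaller share of root tissue as the whole cause only if all 13 are expressed in root alone. Otherwise this spread does not decide the question. A loss of particular root cells and a change of expression within cells both stay open and were not tested.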
